A study of Mus musculus with 33 samples.

How the data were processed

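Lung miRNA was measured on 33 one-colour microarrays, 1 array per mouse, from female C57BL/6 mice, a common inbred laboratory strain. The mice received 0.162 mg of Printex 90, a carbon black made of nanosized particles, or vehicle alone by instillation into the trachea, and were killed 1, 3 or 28 days later. The vehicle was 0.9% NaCl in water with 10% acellular bronchoalveolar lavage fluid, per the labels' protocols. Treatment and day were taken from the sample labels, which gave 6 control arrays on each day and 6, 4 and 5 exposed arrays on days 1, 3 and 28. The series design names 6 individual mice per group, so the arrays of a group were treated as separate animals. Replicate numbers run through the whole series and each names 1 array, so they pair no samples.

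Total RNA enriched with small RNA was labelled with Cy3 and hybridised to Agilent mouse miRNA arrays, per the labels' protocols. The deposited scanner files hold spot brightness as intensity on a linear scale, extracted with Feature Extraction 10.7.3.1, and their processed signal is background-subtracted, per the file headers. No normalization between arrays by the authors is recorded in those headers. The series table deposited by the authors holds 1 log2 value per miRNA and array, and how the authors made these values is not given in the sources used here. Set against the scanner values of the same arrays, its columns correlated at 0.991 to 1.00 with the log2 median signal, so its scale was read as log2 and its direction as brighter meaning higher. Its column medians lay between 5.41 and 5.43, and how the authors centred or scaled the columns stayed unknown, so it was used only as an alternative. The builds of the miRNA annotation and any further filter of the authors are not given in the sources used here.

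Each array carried 13715 spots, of which 13000 were not controls, for 1857 probes of 650 miRNAs (611 of mouse and 39 of herpesviruses). Control spots and spots with outlier flags, 2.30% of spots, were left out, and no probe was saturated. The mean processed signal over the remaining spots of a probe was divided by a factor per array that made the 75th percentile over the 156 probes detected on all 33 arrays equal, then set to at least 1 and taken to log2. A miRNA was represented by its probe with the highest mean. Where a miRNA had more than 1 bright probe, the probes differed in the sign of the change for 14, 17 and 13 of 61 miRNAs at days 1, 3 and 28. A miRNA counted as above background on an array when most of its unflagged spots for any of its probes were well above background, and it was tested when this held on at least 4 arrays of at least 1 group, which left 172 miRNAs. For a miRNA above background on no array of a group only a bound is given, the mean of the brighter group against the mean over the dimmer group of, per array, the higher of the lowest signal among probes above background and the probe's own signal. In list medians with bounds such a member stands at its bound, or at a log2 change of 0 where the bound allowed no fold. Names are those of the array's design. Of the 611 mouse names, 525 matched 1 gene of the GRCm38.p6 gene table, 4 matched several and 82 matched none.

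All 33 arrays entered 1 linear model of 6 group means in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with lmFit and eBayes with an intensity trend. Contrasts were exposed minus control at each day, the 3 differences of these changes between days, their mean over the 3 days, and an F test over the control days. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a contrast, and 0.05 was the threshold. There were 20 lists of miRNAs: markers of myeloid, lymphoid, erythroid, epithelial, ciliated, endothelial, smooth muscle, fibroblast, heart and skeletal muscle cells and of liver and brain; miRNAs induced in inflammation; the paralogs of the cluster of miR-17 to miR-92a; the let-7, miR-29, miR-30 and miR-15/16 families; p53-responsive miRNAs; miR-210 for hypoxia; the Dlk1-Dio3 cluster; and the viral probes. The 16 lists with at least 2 tested members were tested with camera at a preset correlation of 0.01 in each exposure contrast, adjusted over 48 tests, and again with an estimated correlation. Camera on the mean effect and on the differences between days, adjusted over 64 tests, was chosen after seeing the data. Brightness of groups was compared with exact permutation tests.

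The miRNAs named were fixed by rule: per exposure contrast the 12 largest rises and 12 largest falls past the threshold, leaving out those below background in both groups; up to 15 past it in 1 direction at all 3 days; members of a list as its examples; and the 8 with the smallest adjusted p for each difference between days and for the control days. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined. The alternatives were normexp background correction with an offset of 50, the total gene signal, quantile normalization, the 75th percentile over all probes, no scaling, a floor of 10, the mean over probes, no filter, only miRNAs detected on all arrays, no trend, a robust fit, slide as fixed or random block, scan day as block, the series table, other thresholds, only the groups of 1 day, and each array left out in turn. The files hold no mean spot signal, so normexp was run on the median signal. Leaving out slide 1 was added after seeing the data. Its pairs go against the other slides in miR-21, miR-146b and miR-689. Runs without it therefore favour these miRNAs and give no independent support for them.

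The procedure was tested on simulated data with 30 of 172 miRNAs changed. At day 1 it recovered 64.0% of 1.5-fold, 87.5% of 2-fold and 99.0% of 3-fold changes, at day 3 it recovered 59.0%, 83.5% and 96.5%, and at day 28 it recovered 61.0%, 84.5% and 97.5%, with 1.18%, 4.02% and 4.33% of calls false. The simulation shuffled the residuals of the fit over all arrays, which kept neither the slides nor the unequal spreads of the groups. With 30 changed miRNAs the adjustment is also milder than with few. Recovery in the real data may therefore be lower, and a lack of calls does not exclude 2-fold changes. Lists with no change, simulated at the group sizes of day 3, reached an unadjusted p under 0.05 in 22.8% of 320 tests with the preset correlation and in 5.00% with an estimated one, so the preset test is too liberal for these lists. List tests under all other settings, also with blocks and without slide 1, used the preset correlation only. Their p-values are too liberal in the same way. A list raised 1.5-fold was found in 20 of 20 draws with the preset and in 15 of 20 with an estimated correlation. The number of arrays limits the precision of all values.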

Results

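Pulmonary miRNA was compared between carbon black exposed and vehicle control mice over a time course of 1, 3 and 28 days after a single instillation. The control groups held 6, 6 and 6 mice and the exposed groups 6, 4 and 5 mice at days 1, 3 and 28. Between 99 and 193 of 611 mouse miRNAs were above background on an array, 395 were so on none of the 33 arrays, and 94 miRNAs were so on all. The 75th percentile of the processed signal over the 156 probes detected on all arrays ranged from 187 to 1211 units before scaling. It averaged 472 ± 288 (SD) in controls and 654 ± 95.6 in exposed lungs at day 1, 709 ± 310 and 628 ± 117 at day 3, and 956 ± 215 and 653 ± 285 at day 28. Folds of brightness and their tests used means of log2 values, not the averages above. Control arrays of day 28 were 2.28-fold brighter than those of day 1 (exact permutation p = 0.0130, Benjamini-Hochberg adjusted p = 0.0779 over 6 comparisons). Exposed arrays were 1.58-fold brighter than controls at day 1 (exact p = 0.0779) and 1.53-fold dimmer at day 28 (exact p = 0.0649), both with an adjusted p of 0.156. The median number of mouse miRNAs above background was 129 in control and 162.5 in exposed lungs at day 1, and 175.5 and 138 at day 28. The background flag is set per array before scaling. A count of arrays above background that favours the brighter group of a day may therefore reflect brightness, which was not tested. The arrays lay on 9 slides read on 5 days, and each of 15 exposed arrays shared a slide with a control of its day. Controls and exposed arrays held different positions on every slide, so position and exposure cannot be told apart. The 4 arrays of slide 1 stood apart on the first principal component over 94 miRNAs (32.7% of the variance), at -5.92 to -2.73 against -1.66 to 1.99 elsewhere.

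**Figure D1:**
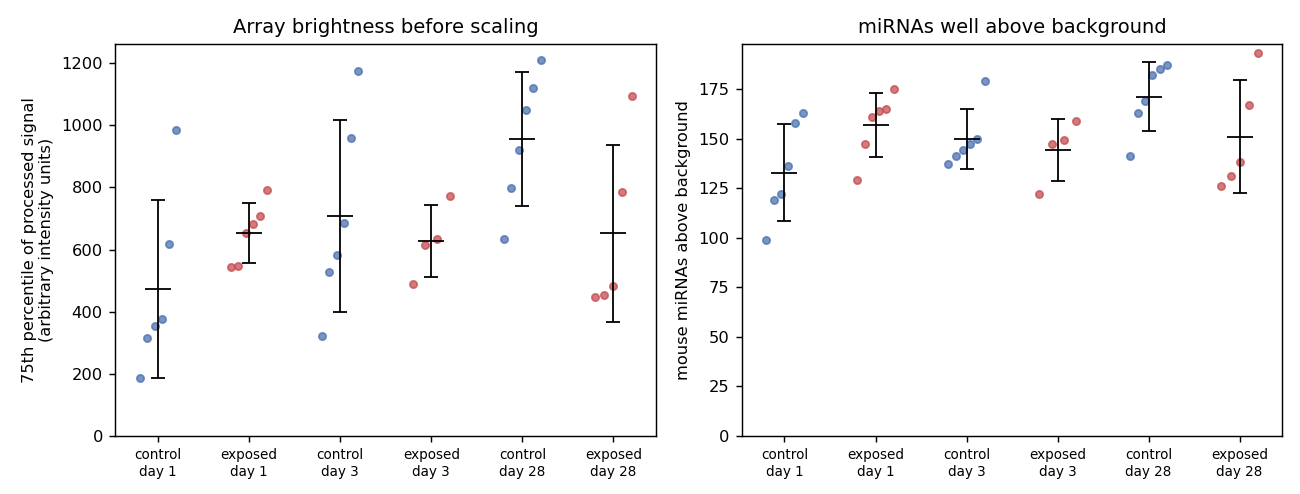
Brightness of each array before scaling, as the 75th percentile of the processed signal over the probes detected on all arrays, and the number of mouse miRNAs above background, by group; points are arrays and bars mark the mean ± SD. Control arrays of day 28 averaged 956 and those of day 1 472 signal units.

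At day 1 the question was which miRNAs differed soon after instillation. miR-223, abundant in neutrophils, had a mean log2 signal of 9.08 ± 0.56 (SD, n = 6) in exposed and 8.26 ± 0.27 (SD, n = 6) in control lungs, a log2 change of 0.82 ± 0.21 (SE, adjusted p = 0.0994) or 1.76-fold, and was higher in 6 of 6 pairs on the same slide. The other members of the myeloid list, miR-142-3p and miR-142-5p, had log2 changes of 0.51 ± 0.31 and 0.43 ± 0.21 (adjusted p = 0.487 and 0.485). miR-155, induced in activated macrophages and lymphocytes, was above background in 4 of 6 exposed and 0 of 6 control lungs (adjusted p = 0.212), and its signal allowed no fold above the background bound. miR-222, singled out after its values were seen, had the same counts of 4 and 0 (adjusted p = 0.118) and no fold either. Both counts favour the exposed arrays, the brighter group of day 1, and may reflect brightness. miR-21 had a log2 change of 0.41 ± 0.22 and was higher in 5 of 6 pairs, miR-146b 0.33 ± 0.32, and miR-146a, a feedback regulator of NF-kB signalling, -0.060 ± 0.17. A further, dimmer probe above background on all 33 arrays gave a log2 change of 0.46 for miR-223 and 0.87 for miR-21. Among the 172 miRNAs tested, limma called 0, with 9 higher and 7 lower at an unadjusted p under 0.05, and the median log2 change was -0.097.

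Of the 3 members of the myeloid list 0 rose or fell over all miRNAs tested and 1, miR-223, was higher when adjusted over the list alone (adjusted p = 0.00173). The others, miR-142-3p and miR-142-5p, are named as the arms of 1 precursor and are not independent, and the list's median is the value of miR-142-3p. Whether they mark myeloid cells alone was not tested. The list's median log2 change was 0.51 (camera adjusted p = 0.00202), above 0 under each of 6 scalings (0.46 to 1.17), and the call was lost with an adjusted p = 0.134 with an estimated correlation. It was 0.51 with slide as a fixed or random block (adjusted p = 0.00485 and 0.00217), positive in 5 of 6 pairs on the same slide (-0.14 to 1.15), and 0.41 without slide 1 (adjusted p = 0.00167). Each slide with an exposed array of day 1 held 1 control of that day. A slide block therefore cannot move any day 1 change, only its p-value. The myeloid call ended with total gene signal (0.47, adjusted p = 0.188) and with the series table (0.50, adjusted p = 0.0653). The median was 0.26 without control day 1 replicate 1 (adjusted p = 0.0326). Of the 4 tested miRNAs induced in inflammation 3 had higher fitted values, miR-155 with no fold above its bound. Of the 4, 0 were past the threshold and 1, miR-155, when adjusted over the list alone (adjusted p = 0.0148). Their median was 0.37, or 0.16 with miR-155 at its bound, and -0.13 under normexp, though above the median of all miRNAs under each of 6 scalings (0.13 to 0.46; camera adjusted p = 0.0505, and adjusted p = 0.832 with an estimated correlation). It was 0.37 with either block, at an adjusted p of 0.0701 with the fixed and 0.0493 with the random block, positive in 5 of 6 pairs (-0.31 on slide 1 to 0.94), and 0.53 without slide 1 (adjusted p = 0.0244). Of the 9 let-7 family members, which act in differentiation and growth control, 9 had negative changes, 0 past the threshold over all miRNAs or adjusted over the list alone. The let-7 median was -0.20, but 0.46 without scaling, or -0.26 to 0.21 relative to the median of all (adjusted p = 0.0505, and adjusted p = 0.868 with an estimated correlation), with let-7c at -0.22 ± 0.11 (SE) and let-7b at -0.22 ± 0.12. It was -0.20 with either block (adjusted p = 0.00964 and 0.0245), negative in 5 of 6 pairs (-0.44 to 0.0085), and -0.14 without slide 1 (adjusted p = 0.0262). These block and slide runs used the preset correlation of 0.01, where the estimated let-7 correlation was 0.78, so their p-values are too liberal. miR-223 passed the threshold without control day 1 replicate 13 (0.92, adjusted p = 0.0370), exposed day 1 replicate 3 (1.02, 0.00156) or control day 3 replicate 25 (0.82, 0.0467), the last with miR-222 (0.0166), and miR-155 without exposed day 28 replicate 12 (0.00958). Replicate 12 lay apart from the other exposed arrays of day 28 in miR-155, so leaving it out narrows the shared spread. miR-223 passed also with slide as a random block (0.82, adjusted p = 0.0229, as for miR-222), not with the fixed block (0.82, 0.0806, as for miR-222), and without slide 1 (0.97, 0.00304), where miR-689 passed too (1.59, 0.0456). The day 1 pair of slide 1 goes against this change of miR-689 (-0.997), so removing that slide raises it by construction. Under other scalings miR-223 passed with quantile normalization (adjusted p = 0.0187), the percentile over all probes (0.0182) and no scaling (0.00628), and it passed among miRNAs detected on all arrays (0.0473). miR-155 passed in the first 3 of these (0.0187, 0.0182 and 0.0247) and with total gene signal (0.0252), and miR-222 in the first 3 (0.0187, 0.0117 and 0.0197) and with the mean over probes (0.0162). miR-139-5p, singled out after its values were seen, passed with total gene signal (0.0252), quantile normalization (0.0213) and no scaling (0.0294).

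At day 3 the same comparison was made for 4 exposed and 6 control lungs. The erythroid miR-144 and miR-451, which lie next to each other in the genome and act in red cell maturation, had mean log2 signals of 8.63 ± 0.41 (SD, n = 4) and 12.92 ± 0.52 in exposed lungs against 8.16 ± 0.38 (SD, n = 6) and 12.50 ± 0.34 in controls. Their log2 changes were 0.46 ± 0.26 and 0.42 ± 0.24 (SE), and that of miR-486, also erythroid, was 0.56 ± 0.25 (adjusted p = 0.996 each). miR-144 was higher in 4 of 4, miR-486 in 3 and miR-451 in 2 pairs on the same slide. The heart and skeletal muscle miRNA miR-1 had 5.29 ± 0.82 against 6.68 ± 0.96 in controls, a log2 change of -1.39 ± 0.84, and miR-133b, above background in 2 of 4 exposed and 5 of 6 control lungs, -1.35 ± 0.80 (adjusted p = 0.996 each). Both were lower in 4 of 4 pairs. miR-133a was above background in 0 of 4 exposed and 2 of 6 control lungs, which allowed no fold. Limma called 0 of 172 miRNAs, with 2 higher and 0 lower at an unadjusted p under 0.05, and the median log2 change was -0.036.

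Of the 3 erythroid markers 3 were higher, 0 past the threshold over all miRNAs tested or adjusted over the list alone (smallest adjusted p = 0.0847). Their median was 0.46 (camera adjusted p = 0.000129), above 0 under each of 6 scalings (0.35 to 0.48), and the call was lost with an adjusted p = 0.130 with an estimated correlation. It was 0.43 and 0.44 with slide as a fixed and random block (adjusted p = 0.00752 and 0.000889), positive in 3 of 4 pairs (-0.035 to 1.51), and 0.64 without slide 1 (adjusted p = 0.00167). Of the 3 tested muscle markers 3 had lower fitted values, miR-133a with no fold beyond its bound. Of these 3, 0 were past the threshold or adjusted over the list alone (smallest adjusted p = 0.119). Their median was -1.35, also with miR-133a at its bound, and below 0 under each of 6 scalings (-1.67 to -0.29), with a camera adjusted p of 0.00561 that was lost with an adjusted p = 0.527 with an estimated correlation. It was -1.72 and -1.58 with slide as a fixed and random block (adjusted p = 0.000143 and 0.000463), negative in 4 of 4 pairs (-3.17 to -0.94), and -1.46 without slide 1 (adjusted p = 0.0248). The muscle call was lost without control day 3 replicate 14 (median -1.03, adjusted p = 0.0684), with the series table (-0.29, 0.0825) and with no filter on detection (-0.15, 0.183). miR-21 had a log2 change of 0.27 ± 0.25 (SE), miR-146b 0.27 ± 0.36, miR-223 0.20 ± 0.24 and miR-146a -0.075 ± 0.20. miR-155 was above background in 0 of 4 exposed and 1 of 6 control lungs. The 4 inflammation miRNAs had a median of 0.097 that no scaling turned (camera adjusted p = 0.653). It was 0.16 and 0.14 with slide as a fixed and random block (adjusted p = 0.343 and 0.434) and 0.34 without slide 1 (adjusted p = 0.230). The 3 myeloid markers had a median of 0.016 that turned under 4 of 6 scalings (adjusted p = 0.869). In both lists 0 members passed the threshold, over all miRNAs or adjusted over the list alone. Of the 9 let-7 members 9 were negative, 0 past either threshold, with a median of -0.11 that no scaling turned (-0.18 to -0.058; adjusted p = 0.0505, and adjusted p = 0.868 with an estimated correlation). With the fixed and random block it was -0.14 and -0.13 (adjusted p = 0.00752 and 0.0183). It was negative in 4 of 4 pairs (-0.25 to -0.020). It was -0.14 without slide 1 (adjusted p = 0.00167). These let-7 runs with blocks and without slide 1 used the preset correlation only. Without slide 1, whose removal was chosen after seeing the data, limma called 1 miRNA at day 3, miR-689 (2.11, adjusted p = 0.0199).

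**Figure D2:**
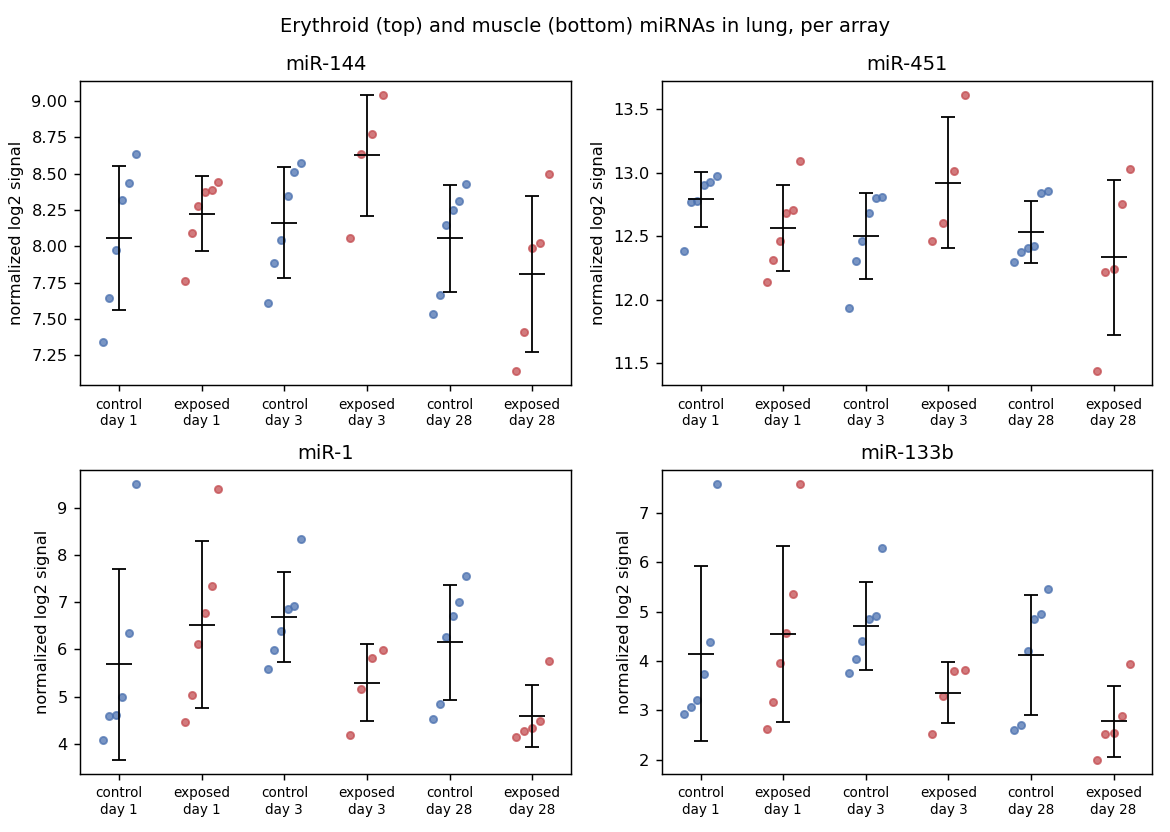
Normalized log2 signal of erythroid and of heart and skeletal muscle miRNAs by group; points are arrays and bars mark the mean ± SD. At day 3 miR-144 averaged 8.63 in exposed and 8.16 in control lungs and miR-1 averaged 5.29 and 6.68, with 0 of them past the threshold.

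At day 28 the list of miRNAs induced in inflammation had the highest median over controls of the 16 lists. miR-21, raised in injured and fibrotic tissue, had a mean log2 signal of 12.52 ± 0.75 (SD, n = 5) in exposed and 11.67 ± 0.11 (SD, n = 6) in control lungs, a log2 change of 0.85 ± 0.23 (SE, adjusted p = 0.157) or 1.81-fold. miR-146b, a relative of miR-146a, had 6.92 ± 1.15 against 5.78 ± 0.13, a log2 change of 1.14 ± 0.34 (adjusted p = 0.166) or 2.20-fold. The log2 changes of miR-146a and miR-155 were 0.48 ± 0.18 and 0.75 ± 0.31, or 1.40-fold and 1.68-fold (adjusted p = 0.570 each), miR-155 being above background in 4 of 5 exposed and 4 of 6 control lungs. All 4 were higher in 4 of 5 pairs on the same slide. Limma called 0 of 172 miRNAs, with 9 higher and 4 lower at an unadjusted p under 0.05, and the median log2 change was -0.034.

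Of the 4 tested inflammation miRNAs 4 were higher, 0 past the threshold over all miRNAs and 4 when adjusted over the list alone (adjusted p = 0.00366 for miR-21, 0.00385 for miR-146b, 0.0175 for miR-146a and 0.0222 for miR-155). These p-values rest on 1 spread shared by all groups (residual SD 0.38, 0.55, 0.30 and 0.51 in that order). The exposed lungs of day 28 spread more widely than this in each of the 4, so the p-values may be too small. The list's median was 0.80 (camera adjusted p = 1.81e-07), above 0 under each of 6 scalings (0.19 to 0.80), and the call was lost with an adjusted p = 0.0518 with an estimated correlation. It was 0.79 and 0.80 with slide as a fixed and random block (adjusted p = 8.79e-06 and 1.14e-06), positive in 4 of 5 pairs (-0.39 on slide 3 to 1.74), and 0.83 without slide 1 (adjusted p = 7.29e-06). With no filter on detection, which added 7 members too dim to test otherwise, its median was 0 (adjusted p = 0.0103). Without exposed day 28 replicate 12, which lay at or below the level of the controls, limma called all 4: miR-21 (1.09, adjusted p = 0.00205), miR-146b (1.4975, 0.00231), miR-146a (0.67, 0.0201) and miR-155 (1.22, 0.00100). That array goes against the other exposed arrays, so leaving it out raises these changes and narrows their spread. These 4 calls are therefore no independent support for a rise. miR-21 also passed without slide 1 (0.88, 0.0314) and with quantile normalization (0.68, 0.0488), and miR-146b with normexp (1.02, 0.0101). miR-155 passed with a floor of 10 (0.76, 0.00283). That floor lies above its mean signal in day 1 controls and in both groups of day 3, so it evens out those values and narrows the shared spread. With slide as a fixed and random block the adjusted p of miR-21 was 0.236 (0.84) and 0.0513 (0.85). The muscle miRNA miR-1 had a log2 change of -1.55 ± 0.79 (SE, adjusted p = 0.633) and was lower in 5 of 5 pairs. miR-133b was above background in 0 of 5 exposed and 4 of 6 control lungs, at least 1.58-fold lower (adjusted p = 0.742), and miR-133a had the same counts with no fold above its bound. Both counts favour the controls, the brighter group of day 28. The 3 muscle markers, 0 past either threshold, had a median of -1.35, or -0.66 with both bounds, and 0.078 under normexp, or -1.84 to -0.20 relative to the median of all miRNAs under 6 scalings (camera adjusted p = 0.0505, and adjusted p = 0.832 with an estimated correlation). With the fixed and random block it was -1.25 and -1.29 (adjusted p = 0.0339 and 0.0416), negative in 5 of 5 pairs (-1.97 to -0.075), and -1.32 without slide 1 (0.0832). The erythroid markers, 3 lower and 0 past either threshold, had a median of -0.20 that no scaling turned (-0.81 to -0.083; camera adjusted p = 0.586), with log2 changes of -0.25 ± 0.24 (SE) for miR-144 and -0.20 ± 0.22 for miR-451. Myeloid markers were 3 higher, 0 past either threshold, with a median of 0.15 that turned under 2 of 6 scalings but lay 0.045 to 0.24 above the median of all miRNAs (adjusted p = 0.369) and miR-223 at 0.12 ± 0.22. Of the 9 let-7 members 9 were negative, 0 past either threshold, with let-7c at -0.24 ± 0.12 and a median of -0.14, but 0.037 with the series table, or -0.44 to 0.042 relative to the median of all (adjusted p = 0.0515, and adjusted p = 0.868 with an estimated correlation). With either block the let-7 median was -0.14 at an adjusted p of 0.0228 with the random and 0.00752 with the fixed block. It was negative in 4 of 5 pairs (-0.36 to 0.013). It was -0.11 without slide 1 (adjusted p = 0.0262). As at the other days, the let-7 runs with blocks and without slide 1 used the preset correlation only.

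**Figure D3:**
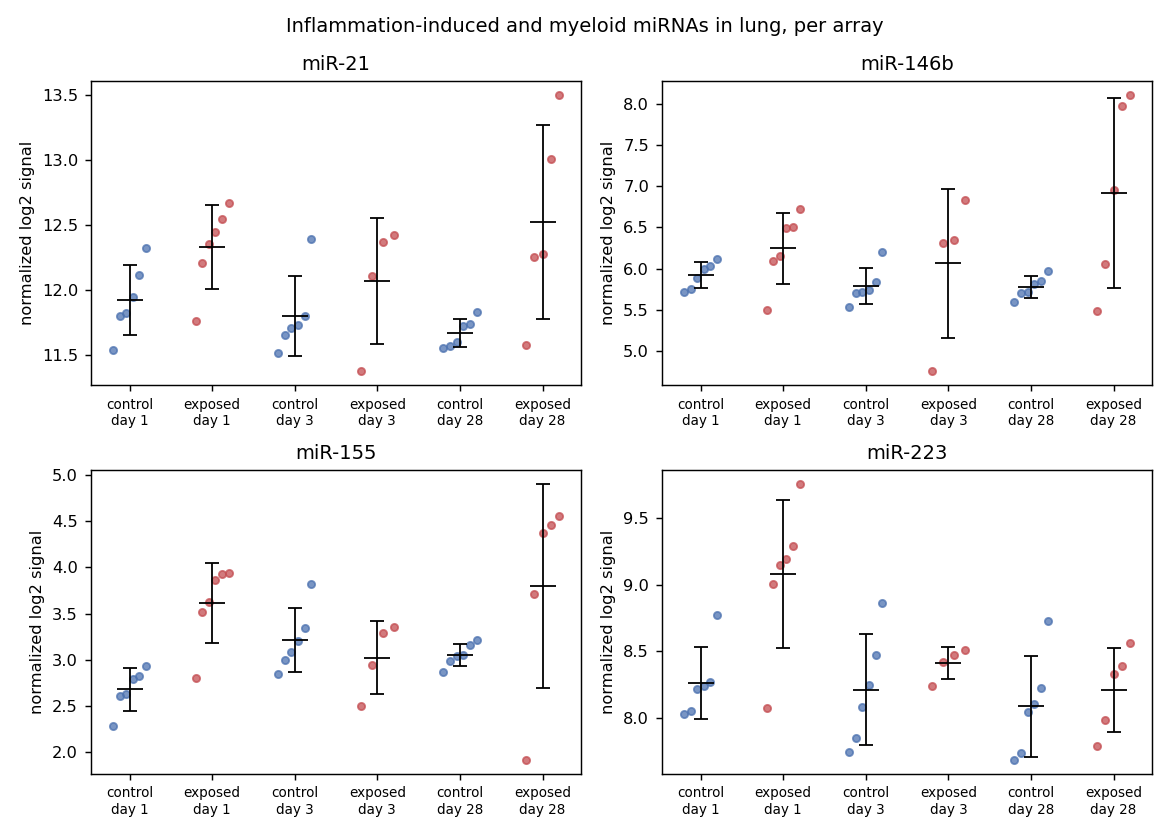
Normalized log2 signal of miR-21, miR-146b, miR-155 and miR-223 by group; points are arrays and bars mark the mean ± SD. At day 28 miR-21 averaged 12.52 in exposed and 11.67 in control lungs, and 1 exposed array, replicate 12, lay at or below the level of the controls in miR-21, miR-146b and miR-155.

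Averaged over the 3 days, the design asked which miRNAs responded over the whole time course. miR-689 was the 1 miRNA called by limma among 172 and rose by a log2 change of 1.32 ± 0.31 (SE, adjusted p = 0.0333), or 2.50-fold. It lies outside the naming rule and was singled out after its values were seen. Its log2 changes were 1.17 ± 0.51, 1.40 ± 0.57 and 1.39 ± 0.54 at days 1, 3 and 28, and it was higher in 13 of 15 pairs on the same slide. It was a dim miRNA, above background in 2, 1 and 3 of 6 controls and in 5 of 6, 3 of 4 and 4 of 5 exposed lungs. A further probe for it was above background on 0 arrays, and its name matched no gene of the reference. Its call ended with normexp (0.21, adjusted p = 0.996), a floor of 10 (0.49, 0.256), the series table (0.14, 0.0745), the percentile over all probes (1.29, 0.0869) and no filter on detection (1.32, 0.105). miR-21 followed at 0.51 ± 0.14 (adjusted p = 0.0596) or 1.42-fold, higher in 5 of 6, 3 of 4 and 4 of 5 pairs. miR-146b had 0.58 ± 0.20, miR-223 0.38 ± 0.13 and let-7c -0.21 ± 0.068 (adjusted p = 0.217 each), let-7c being lower in 14 of 15 pairs. At an unadjusted p under 0.05 there were 7 higher and 10 lower miRNAs.

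In list tests of the mean effect, chosen after seeing the data, the inflammation median was 0.50, or 0.38 with miR-155 at its bounds at days 1 and 3, with 4 of 4 higher and 3 when adjusted over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.185 with an estimated correlation). The myeloid median was 0.29 with 3 of 3 higher and 1 when adjusted over the list alone (0.0263, and adjusted p = 0.423 with an estimated correlation). The let-7 median was -0.14 with 9 of 9 lower and 1 when adjusted over the list alone (0.00360, and adjusted p = 0.778 with an estimated correlation), though single days turned under scalings as given above. With slide as a fixed block limma called 14 miRNAs for the mean effect. The 4 higher were miR-689 (1.20, adjusted p = 0.0327), miR-146b (0.63, 0.0345), miR-21 (0.52, 0.0345) and miR-126-5p (0.46, 0.0377). The 10 lower were let-7a, let-7b, let-7c, let-7d, let-7g, miR-139-3p, miR-151-5p, miR-195, miR-497 and miR-542-5p. A random block gave 4 calls, miR-689 (1.24, 0.00822), miR-21 (0.52, 0.0245), let-7c (-0.21, 0.0245) and miR-146b (0.61, 0.0407). Without slide 1 there were 5, miR-689 (1.71, 3.04e-05), miR-21 (0.70, 0.000736), miR-223 (0.48, 0.0116), miR-146b (0.77, 0.0169) and miR-1224 (0.48, 0.0387). On that slide miR-21, miR-146b and miR-689 were lower on the exposed array, by a mean of -0.65 at day 1 and -1.18 at day 3. Removing it raises these miRNAs by construction, so their calls without it are no independent support. The call of miR-689 was lost without any 1 of 18 of the 33 arrays (replicates 7, 8, 11, 14, 15, 16, 17, 18, 20, 21, 22, 24, 27, 29, 30, 31, 32 and 33), with its adjusted p at most 0.0764, and 0 miRNAs were then called. There were 2 calls without replicate 1, 2 or 25, 3 without replicate 3, 4 without replicate 4 and 5 without replicate 12.

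**Figure D4:**
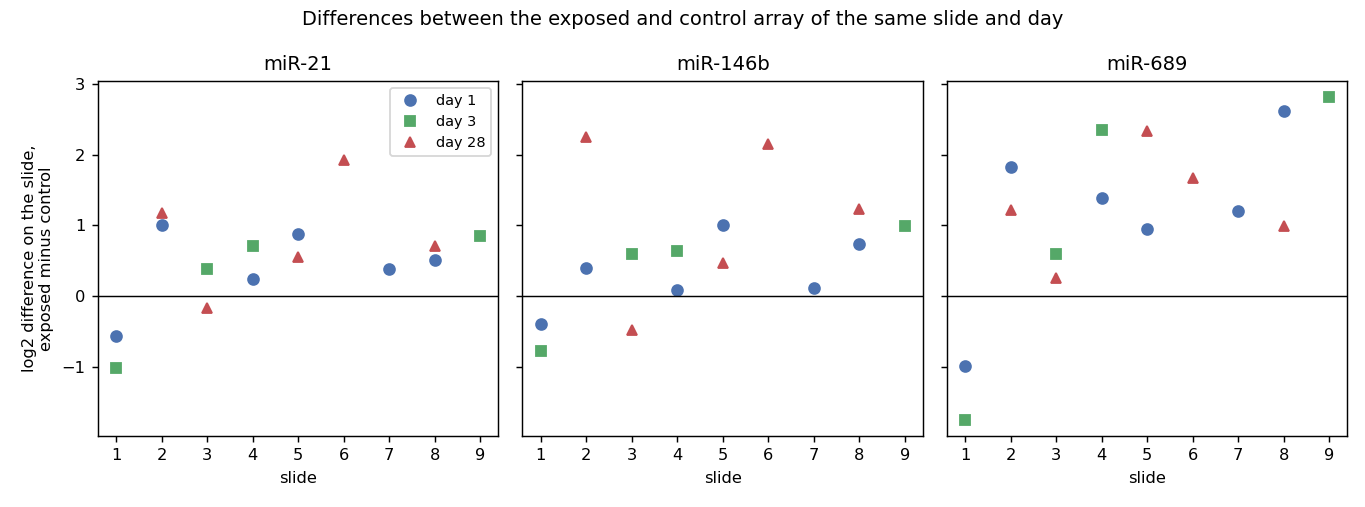
Log2 difference between the exposed and the control array of the same slide and day, for miR-21, miR-146b and miR-689, against slide number; points are pairs, with symbols for the days. miR-689 was higher on the exposed array in 13 of 15 pairs.

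The change from control was then compared between days. From day 1 to day 3 the change of miR-1 differed by -2.23 ± 1.13 (SE), of miR-455 by 1.04 ± 0.44, of miR-328 by 0.78 ± 0.31, of let-7d* by 0.69 ± 0.31 and of miR-451 by 0.65 ± 0.32, while miR-142-5p and miR-223 each differed by -0.62 ± 0.32. miR-155 was also among the 8 smallest p, with a bound on 1 side of each day, and all 8 had an adjusted p of 0.990. From day 1 to day 28 the differences were 1.33 ± 0.49 for let-7b*, -1.25 ± 0.47 for miR-375, an epithelial and endocrine miRNA, and 1.00 ± 0.31 for miR-877* (adjusted p = 0.489 each, as for miR-222, whose day 1 change was only bounded). They were 1.29 ± 0.50 for miR-702 and 0.47 ± 0.19 for miR-342-3p (adjusted p = 0.527 each), and 0.80 ± 0.36 for miR-207 and -0.69 ± 0.31 for miR-223 (0.572 each). From day 3 to day 28 they were 0.87 ± 0.49 for miR-146b, 0.56 ± 0.27 for miR-146a, -0.71 ± 0.35 for miR-144, -0.67 ± 0.34 for miR-486, -0.62 ± 0.32 for miR-451, -0.33 ± 0.18 for miR-25 and -0.28 ± 0.13 for miR-93, with miR-155 bounded at day 3 (adjusted p = 0.999 each). Limma called 0 of 172 miRNAs in each difference, with 3 higher and 1 lower, 7 higher and 6 lower, and 2 higher and 1 lower at an unadjusted p under 0.05. Without control day 1 replicate 5 it called miR-702 from day 1 to day 28 (1.67, adjusted p = 0.0483), and without exposed day 28 replicate 12 miR-155 from day 3 to day 28 (adjusted p = 0.0163). Replicate 12 lay at or below the level of the controls in miR-155, so leaving it out raises this difference by construction. Total gene signal gave a call of miR-155 from day 1 to day 3 (adjusted p = 0.0364), and from day 1 to day 28 the percentile over all probes gave one of miR-222 (0.0498) and no filter one of miR-135b (0.0102). With normexp and without scaling the second difference had 97 and 119 calls, where the median of all miRNAs moved to 0.64 and -1.25.

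Control lungs were compared over the days as a background for these changes. miR-542-5p fell by 1.03 ± 0.24 (SE, log2) from day 1 to day 28 (F test adjusted p = 0.0170), above background in 3, 6 and 5 of 6 controls at days 1, 3 and 28. miR-877* fell by 0.94 ± 0.22 (adjusted p = 0.0438). The next 6 did not pass (adjusted p = 0.0770 each): miR-140 differed by -0.60 ± 0.15, miR-542-3p by -0.48 ± 0.22, miR-218 by -0.47 ± 0.14, miR-28 by -0.42 ± 0.12, miR-181c by -0.40 ± 0.16 and miR-29b, of the miR-29 family that represses collagen genes, by 0.39 ± 0.12. Limma called 2 of 172 miRNAs, with 31 at an unadjusted p under 0.05. Both calls ended with total gene signal (adjusted p = 0.285 for miR-542-5p and 0.0707 for miR-877*), quantile normalization (0.212 and 0.178), the percentile over all probes (0.365 and 0.456) and the series table (0.166 and 0.169). miR-877* was also lost with the mean over probes (0.0646), no filter (0.0550), slide or scan day as a fixed block (0.0785 and 0.0627) and without slide 1 (0.0852). Without scaling both fallers turned, to 0.16 for miR-542-5p and 0.25 for miR-877*, where the median of all miRNAs was 1.01. miR-877* was lost without any 1 of 24 arrays (adjusted p at most 0.122) and miR-542-5p without control day 28 replicate 6, 18, 28 or 32 (at most 0.0778). In 20 of these omissions 1 call was left (replicates 1, 3, 7, 8, 10, 11, 12, 13, 15, 16, 19, 20, 22, 23, 25, 26, 27, 29, 30 and 33). There were 9 calls without replicate 24, 6 without replicate 5 and 5 without replicate 17, all controls of day 1. With slide as a fixed block 1 call was left, miR-542-5p (0.0358), and a random block gave 12.

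Of the 48 list tests 4 were called, the 4 described above, and 0 with an estimated correlation. There were 7 to 12 calls without any 1 of replicates 1, 4, 6, 14, 15, 16, 17, 23, 25, 26, 29 and 30. None of the remaining lists of at least 2 members had a member past the threshold over all miRNAs or adjusted over the list alone, and their medians below, at days 1, 3 and 28, turned under at least 1 scaling except where said. Relative to the median of all miRNAs, which those scalings also moved, 5 of them did not turn. These were ciliated (0.052 to 0.34), miR-17 to miR-92a (0.024 to 0.17) and p53 (0.083 to 0.21) at day 1 and fibroblast (-0.24 to -0.025) and liver and brain (0.059 to 0.18) at day 28. The miR-30 median at day 3 did turn (-0.082 to 0.018). The 4 lymphoid markers had medians of -0.13, -0.12 (no turn) and 0.048 (camera adjusted p = 0.613, 0.232 and 0.653). The 6 epithelial markers of the miR-200 group had 0.052, -0.077 (no turn) and -0.0089 (0.503, 0.586 and 0.982). The 3 ciliated cell markers had 0.12, -0.33 and -0.21, the last 2 without a turn (0.815, 0.721 and 0.653). The 2 endothelial miRNAs, miR-126-3p and miR-126-5p, had 0.15, 0.21 (no turn) and 0.031 (0.869, 0.667 and 0.653). The 4 fibroblast markers had -0.14, 0.0069 and -0.079 (0.586, 0.653 and 0.653). The 2 liver and brain markers had 0.13, 0.18 and 0.14 (0.869 each), and the liver miRNA miR-122 spread by a residual SD of 2.10 and was above background on 21 arrays. The 3 muscle and 3 erythroid markers had 0.64 and -0.022 at day 1 (0.303 and 0.869), where miR-1 was at 0.84 ± 0.76 (SE) and miR-451 at -0.22 ± 0.21. The 10 paralogs of the cluster of miR-17 to miR-92a, linked to proliferation, had 0.075, 0.099 (no turn) and -0.024 (0.0505, 0.0505 and 0.722), with 7, 8 and 4 of them higher (adjusted p = 0.832 at days 1 and 3 with an estimated correlation). At day 1 miR-17* was above background in 5 of 6 exposed lungs and in no control. It allowed no fold, so its place among the 7 and its part in the median are fitted values. Its counts too favour the brighter group of day 1. At day 1 this list passed with slide as a random block (0.075, adjusted p = 0.0493) and without slide 1 (0.13, 0.0244), not with the fixed block (0.0701). At day 3 its adjusted p was 0.301 and 0.127 with the fixed and random block. The 3 miR-29 members had 0.21, 0.13 and -0.0038, the first 2 without a turn (0.0916, 0.111 and 0.869). The 5 miR-30 members had 0.0094, -0.065 (no turn) and -0.020 (0.613, 0.653 and 0.869), the 6 miR-15/16 members -0.21, -0.10 (no turn) and -0.070 (0.303, 0.303 and 0.467), and the 4 p53-responsive miRNAs 0.019, -0.17 and -0.13, the last 2 without a turn (0.905, 0.503 and 0.869). The p53 and ciliated lists share miR-34b-5p and miR-34c (-0.33 and -0.42 at day 3), so they are not separate results. The other p53 members, miR-34a and miR-192, were at 0.0014 and -0.0094 at day 3. The miR-15/16 list passed at day 3 with scan day as a block (-0.16, adjusted p = 0.0427), not with slide as a fixed or random block (0.0517 and 0.108) or an estimated correlation (adjusted p = 0.868). Median and test differed in sign for the erythroid and the liver and brain lists at day 1 and for the endothelial and miR-29 lists at day 28, and the ciliated mean was -0.03 at day 1. Of smooth muscle 1 of 3 markers was tested, miR-143, with log2 changes of 0.19, 0.017 and 0.022, and miR-210, induced by hypoxia, had 0.57, 0.086 and -0.23 (adjusted p at least 0.516). None of 53 miRNAs of the Dlk1-Dio3 cluster was tested, and 1 of 39 viral miRNAs, mghv-miR-M1-2, at -0.66, -0.20 and 0.38 (smallest adjusted p = 0.485), which at day 1 had an unadjusted p under 0.05.

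**Figure D5:**
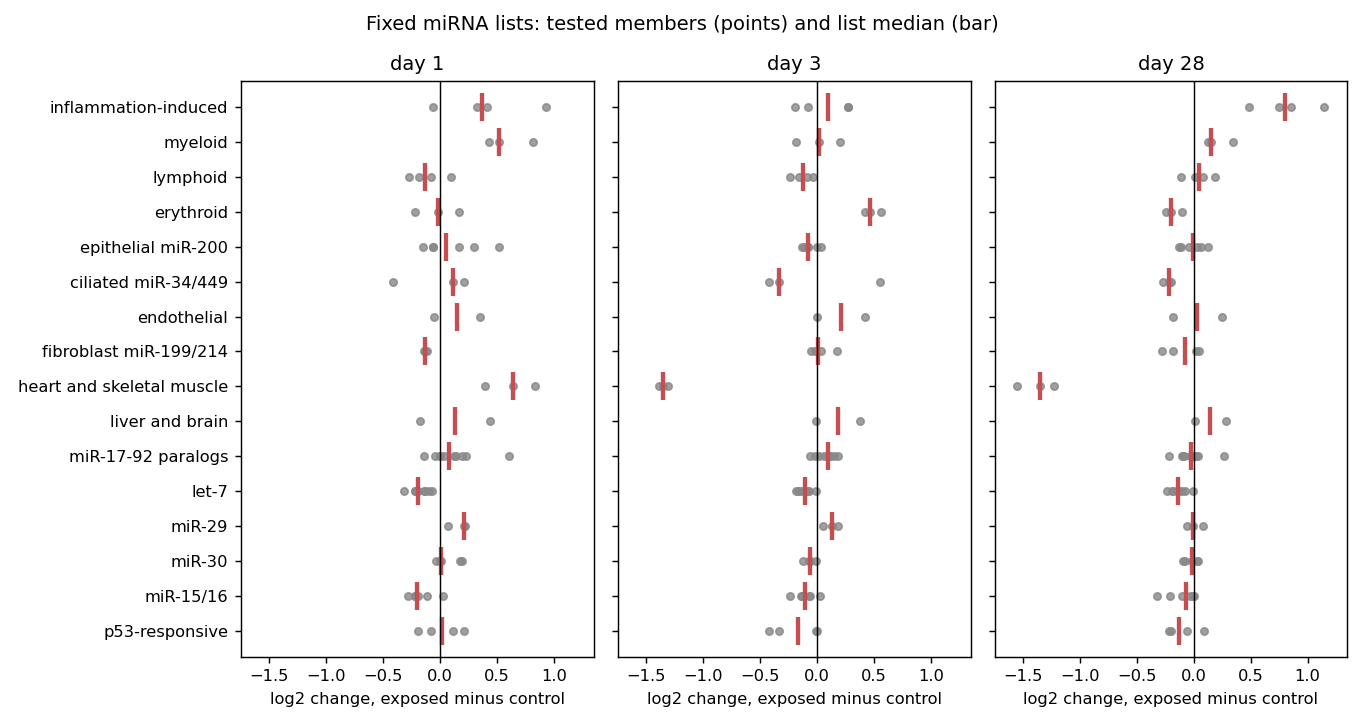
Log2 change, exposed minus control, of the tested members of each list at days 1, 3 and 28; points are miRNAs, drawn at their fitted change also where 1 group was below background, and bars the list medians. The inflammation median was 0.80 at day 28, the myeloid 0.51 at day 1, the erythroid 0.46 and the muscle -1.35 at day 3, the signs of which held under 6 scalings.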

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

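Chosen only after the result was seen were the tests of exchanged labels and of a shared shift on slide 1, of an exchanged label and of low brightness for replicate 12, both tests of muscle content, the exchanges within slides, the list tests between days and the runs without slide 1; the tests of brightness, scaling and other splits were set before.

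Other splits of the arrays, 100 for each result with the real one counted among them, asked whether chance can be excluded. For a real count of 0 calls they can decide nothing, since 100 of 100 splits give 0 or more: the highest other counts were 9 at day 1, 5 at day 3, 3 at day 28 and 11 for the differences between days. Chance could not be excluded for the miRNAs at an unadjusted p under 0.05 at day 1 (27 splits, real 16, highest other 51), day 3 (81 splits, 2 and 58) and day 28 (8 splits, 13 and 19), and for the control days (6 splits, 2 and 28 calls). For the single call of the mean effect the share of splits lay under 0.05 (3 splits, 1 and 2 calls). By the permutation of labels over camera's p it also lay under 0.05 for the myeloid list at day 1 (4 splits, p = 0.000127, smallest other p = 8.37e-06) and the erythroid list at day 3 (1 split, the real one, 5.39e-06 and 9.64e-06). It did not for the muscle list at day 3 (7 splits, 0.000467 and 2.8e-05) or the inflammation list at day 28 (5 splits, 3.77e-09 and 1.52e-11). These 4 lists were those called among 48 tests. The shares are not adjusted for that choice or over the results split, so a share under 0.05 does not exclude chance here. Some splits gave several times the real count, and the source of this was not tested. These splits ignore the slides, so control and exposed labels were also exchanged within the pairs on a slide, with slide as a fixed block and the real labels counted among the exchanges. For the mean effect the share lay under 0.05 (1 of 100 exchanges, the real one, with 14 calls and 1 at most in the others). The exchanges were chosen after the results were seen, and the fixed block gave the most calls of all settings for this effect. The share is not adjusted for that choice. A difference between slide positions would give the same share, so it does not show an effect of exposure. Chance could not be excluded for the myeloid list at day 1 (4 of 32 exchanges, permutation of camera's p, real p = 0.000303, smallest other p = 0.000194). For the inflammation list at day 28 other exchanges gave a camera p as small as the real one (3 of 16 exchanges, 1.83e-07 and 1.81e-08). The same held for the erythroid list at day 3 (3 of 8 exchanges, 0.000941 and 0.00022), so chance could not be excluded for either. For the muscle list at day 3 the real labels alone reached the real p (1 of 8 exchanges, 5.96e-06 and 8.9e-05). In all 3 lists the pairs were too few for a share under 0.05.

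On slide 1 miR-21, miR-146b and miR-689 were lower on the exposed than on the control array in both pairs, by a mean of -0.65 at day 1 and -1.18 at day 3, while 12 of 13 pairs on other slides were positive (-0.13 to 1.92). A shift equal on all arrays of the slide is argued against by construction, since it cancels within a pair, while the pair nearer 0 lay at -0.65, below all pairs of other slides. For exchanged labels in the day 1 pair, its differences over 172 miRNAs correlated with the mean of the other pairs at r = 0.22. This r is across miRNAs, which are not independent, and other pairs gave -0.087 to 0.57 (median 0.29). It goes against an exchange only if the slides share no effect of position, which would give a positive r whichever mouse lies there. Exchanged labels in the day 3 pair remain open at r = -0.094, as does brightness (Spearman rho = -0.25, permutation p = 0.404, and Pearson r = -0.15, p = 0.622, or r = -0.23 without the 2 farthest pairs, over 13 pairs; adjusted p = 0.485 and 0.622 over 3 relations). A difference between these mice stays open and untested.

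Exposed day 28 replicate 12 had miR-21 and miR-146b at a mean log2 signal of 8.53, against 8.64 to 8.86 in the 6 controls and 9.17 to 10.73 in the other 4 exposed lungs. An exchange with a control of that day is argued against, since the highest control lay 0.31 below the lowest other exposed array. Low brightness is argued against by 2 dimmer exposed arrays that lay above all controls, and scaling by the ratio of miR-146b to miR-126-3p within the array, which lay -0.49 from the highest control. A wrong label with no partner in the group, a lower delivered dose or a weaker response of this mouse may each account for it and were not tested.

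miR-1 spread within groups by a residual SD of 1.31 against a median of 0.29 over all miRNAs, and miR-133a and miR-133b by 1.26 and 1.24. miR-1 and miR-133b lay lower in exposed lungs at days 3 and 28. miR-133a was above background on no exposed array of these days and allowed no fold. Different amounts of heart or skeletal muscle in the samples are a candidate explanation: within groups miR-1 followed the mean of miR-133a and miR-133b (Pearson r = 0.98 and Spearman rho = 0.96 over 33 arrays, permutation p = 1e-05 each, the smallest the permutations can give, adjusted 3e-05, and r = 0.97 without the 2 farthest arrays). This is weak evidence, because miR-1 and miR-133a come from shared loci and miR-133a and miR-133b were above background on 10 and 16 arrays. Against it, the muscle miRNAs miR-206, miR-208a, miR-208b and miR-499 were above background on 0 arrays although miR-1 reached 9.51, but levels on different probes cannot be compared and no muscle profile on these probes was at hand, so this does not exclude it. Brightness is open too (Spearman rho = 0.20, permutation p = 0.277, Pearson r = 0.19, p = 0.385, r = 0.26 without the 2 farthest, adjusted p = 0.485 each). An effect of exposure was tested with the list above. It was called at day 3 with the preset correlation and not with an estimated one, and it remains open.

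By Dixon's test 21 of 216 groups held an array apart from the rest, where chance gives about 1 in 20, or 10.8. Exposed day 1 replicate 3 was low for miR-142-3p (9.10) and miR-155 (2.80) and high for miR-25 (7.00). Control day 3 replicate 2 was low for miR-142-3p (8.69) and high for miR-21 (12.40), miR-25 (6.94) and miR-542-5p (5.24), both being arrays of slide 1. High values were miR-1 in exposed day 28 replicate 20 (5.75), miR-133b in control day 1 replicate 17 (7.60), miR-222 in control day 3 replicate 25 (4.79), miR-223 in control day 1 replicate 13 (8.77), miR-28 in control day 1 replicate 1 (6.15), miR-29b in exposed day 1 replicate 7 (10.64) and miR-375 in control day 28 replicate 32 (4.73). Low values were miR-207 in control day 28 replicate 6 (2.41) and exposed day 28 replicate 12 (2.61), miR-29b in exposed day 3 replicate 16 (9.78), miR-342-3p in control day 28 replicate 32 (5.45), miR-451 in control day 1 replicate 24 (12.39) and miR-689 in exposed day 3 replicate 4 (3.44). Control day 3 replicate 14 had 179 mouse miRNAs above background, the other controls of that day 137 to 150.

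Among 48 list tests of the differences between days, 6 passed with the preset correlation and 0 with an estimated one. The tests used fitted values, also for members below background in 1 group. From day 1 to day 3 the myeloid median differed by -0.62 (adjusted p = 0.00371, and adjusted p = 0.214 with an estimated correlation), the erythroid by 0.59 (0.0374 and 0.640) and the muscle by -1.95, or -1.74 with miR-133a at its bound at day 3 (0.00176 and 0.340). From day 1 to day 28 the muscle median differed by -1.87, or -1.05 with miR-133a and miR-133b at their bounds at day 28 (0.0109 and 0.561). From day 3 to day 28 the inflammation median differed by 0.73, or 0.67 with miR-155 at its bound at day 3 (2.48e-05 and 0.185) and the erythroid by -0.67 (0.000389 and 0.185).

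miR-135b, too dim for the filter, was above background on 3 of 5 exposed and 0 of 6 control arrays of day 28, with mean log2 signals of 2.96 and 0.085, at least 1.13-fold higher. With no filter on detection limma called it at day 28 (fitted log2 change 2.88, adjusted p = 0.00322) and in the difference from day 1 to day 28 (3.67, adjusted p = 0.0102).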

How the results depend on the processing

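Chosen only after seeing the data were the runs without slide 1 and those list tests that lie outside the 48 set beforehand. Of 67 named values 34 kept their direction under all alternatives; of 3327 alternatives for them, 992 under other settings and 2135 with 1 array left out kept direction and side of the threshold, 64 and 27 passed it newly, 18 and 46 no longer did, and 42 and 3 reversed. No trend and a robust fit moved no count or list call, and the log2 limit of 0.58 and fitting only the groups of 1 day, run on the counts alone, moved none of these. With only miRNAs detected on all 33 arrays the muscle list and the dimmer named miRNAs have no value. No paired analysis was possible because the groups share no replicate numbers, except by slide, whose pairs and blocks are given with the results. Signal over background limits the dim miRNAs: 395 of 611 mouse miRNAs were on no array above background, and for those below it in 1 group only a bound can be given. Unless said, the cause was not tested.

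Calls at day 1 (0) became 3 with total gene signal, 4 with quantile normalization, 3 with the percentile over all probes, 6 without scaling, 2 with the mean over probes, 3 with no filter, 1 with only miRNAs detected on all 33 arrays (fewer tests), 2 with a random slide block, 1 at an adjusted p under 0.1 and 2 without slide 1. Day 3 (0) gave 1 without slide 1. Day 28 (0) gave 1 each with normexp, quantile normalization, a floor of 10, no filter and without slide 1. Between days, day 3 against day 1 gave 1 with total gene signal, and day 28 against day 1 gave 97 with normexp, 119 without scaling and 1 each with the percentile over all probes and no filter. The mean effect (1) gave 2 each with total gene signal, quantile normalization, the mean over probes and adjusted p under 0.1, 1 each with normexp and no filter, which was miR-21 and miR-1895 in place of miR-689, 0 each with the percentile over all probes, a floor of 10, miRNAs detected on all arrays (which leaves miR-689 untested) and the series table, 14 with a fixed and 4 with a random slide block, 10 with a scan day block and 5 without slide 1. Control days (2) gave 120 with normexp, 117 without scaling, 0 each with total gene signal, quantile normalization, the percentile over all probes and the series table, 1 each with the mean over probes, miRNAs detected on all arrays, a fixed slide block, a scan day block and without slide 1, 5 with no filter and 12 each with a random block and an adjusted p under 0.1. List calls (4) became 11 with normexp, 7 each with total gene signal and quantile normalization, 10 each with a floor of 10 and a random block, 9 each with the mean over probes and without slide 1, 8 each with no filter, a fixed block and a scan day block, 12 at an adjusted p under 0.1 and 0 with an estimated correlation. The median log2 change of all miRNAs moved without scaling to 0.56, -0.11 and -0.65 at days 1, 3 and 28, with normexp to -0.36 and 0.28 at days 1 and 28, with the percentile over all probes to 0.089 and -0.28 at days 1 and 28, and at day 1 with total gene signal to 0.058 and with quantile normalization to 0.0046. In controls from day 1 to 28 it moved from -0.17 to -0.64 with normexp, 0.058 with total gene signal, 0.015 with quantile normalization, 0.26 with the percentile over all probes and 1.01 without scaling. The offset of normexp, fixed before scaling, becomes unequal between arrays after it.

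With an estimated correlation the medians did not move and the calls ended, inflammation at 0.80 (adjusted p = 0.0518), myeloid at 0.51 (0.134), erythroid at 0.46 (0.130) and muscle at -1.35 (0.527). With no filter inflammation at day 28 was 0 (0.0103) and muscle -0.15 (0.183); myeloid was 0.47 (0.188) with total gene signal and 0.50 (0.0653) with the series table, where muscle was -0.29 (0.0825). With 1 array left out, calls ranged from 0 to 2 at day 1, 0 to 0 at day 3, 0 to 4 at day 28, 0 to 0, 0 to 1 and 0 to 1 for the differences, 0 to 5 for the mean effect, 0 to 9 for control days and 4 to 12 for lists; medians ranged from 0.59 to 1.16 for inflammation, 0.26 to 0.70 for myeloid, 0.32 to 0.65 for erythroid and -1.56 to -1.03 for muscle.

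Reversals are of fitted values, also where the text gives only a bound. Reversed with normexp were, at day 1, miR-142-5p (-0.14), miR-146b (-0.14), miR-155 (-0.38), miR-1 (-0.053), miR-133b (-0.40) and miR-222 (-0.36), at day 28 miR-133b (0.078), and between days miR-155 (0.40) and miR-142-5p (0.030) from day 1 to 3, miR-222 (0.84) and miR-375 (0.74) from day 1 to 28, and miR-93 (0.13) and miR-486 (0.042) from day 3 to 28. With the percentile over all probes these were miR-146a at day 1 (0.13), miR-223 at day 28 (-0.12) and in controls miR-181c (0.029) and miR-28 (0.014). Without scaling they were at day 1 miR-146a (0.60), let-7c, let-7b and miR-451 (0.44 each), at day 28 miR-146a (-0.13) and miR-223 (-0.49), between days let-7d* (-0.047), miR-451 (-0.088), miR-877* (-0.28), miR-342-3p (-0.81) and miR-207 (-0.48), and in controls miR-542-5p (0.16), miR-877* (0.25), miR-140 (0.59), miR-218 (0.72), miR-542-3p (0.71), miR-181c (0.78) and miR-28 (0.77). With the series table they were miR-146a at day 1 (0.083) and miR-451 (0.085) and let-7c (0.077) at day 28; with quantile normalization let-7b at day 1 (0.030); with total gene signal miR-207 from day 1 to 28 (-0.30) and in controls miR-542-3p (0.54) and miR-181c (0.45). Leaving out 1 array reversed miR-146a at day 1 (0.012 without exposed day 1 replicate 3), miR-133b at day 1 (-0.22 without exposed day 1 replicate 19, highest 1.08) and miR-451 at day 28 (0.027 without exposed day 28 replicate 23, lowest -0.37).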

Other observations

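The tests described here were all chosen only after the results were seen. Within the exposed lungs of day 28 the inflammation miRNAs spread more widely than in controls, with an SD of 0.75 against 0.11 for miR-21, 1.15 against 0.13 for miR-146b, 0.61 against 0.13 for miR-146a and 1.10 against 0.12 for miR-155 (log2, n = 5 and 6); the difference in spread was not tested. In the 6 controls of day 3, 3 arrays at each of 2 positions on the slide were compared with limma, which called 0 of 172 miRNAs, with 7 at an unadjusted p under 0.05. Both positions held controls on every slide, so this cannot tell whether the positions of exposed arrays differ from those of controls. The 2 sets of arrays also lay on different slides. In the gene table of GRCm38.p6 the genes of miR-144 and miR-451, of miR-1 and miR-133a, and of miR-206 and miR-133b lie next to each other.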
